A study of Mus musculus with 34 samples.

How the data were processed

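Expression was measured by RNA sequencing in 34 samples of splenic B cells of B6.Blimp1GFP/+ mice aged 12 weeks, in 8 groups: follicular (FO) and marginal zone (MZ) B cells sorted fresh (5 samples each), and 6 cultured groups (4 samples each). Per the labels, all cultured groups held the CpG oligonucleotide ODN1826, IL-4 and IL-5, for 72 h (FO) or 48 h (MZ), without a drug or with PD0332991 or rapamycin. Cultured cells were sorted on dilution of a division dye and on the Blimp1-GFP reporter, and fresh cells on CD19, CD93, CD23 and CD21/35. Libraries were made by SMART-Seq HT and Nextera XT. Per the submitters' processing notes, reads were quantified with kallisto against mm10 and normalized with limma (voom), and immunoglobulin genes were removed in one version of each data set. Versions of these tools and the annotation are not given in the sources used here.

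The deposited tables give, for each gene and sample, log2 expression values that the authors normalized by voom, and TPM values that the authors took from kallisto, each with and without immunoglobulin genes. The tables hold 30317 genes with and 29995 without immunoglobulin genes; of the 322 removed genes, 315 are immunoglobulin segments and 7 are others, among them Igj (Jchain). All 34 sample columns matched the labels. TPM columns sum to 89.6% to 95% of the full 1e+06. The log2 values fit the voom formula with an offset of 0.5 added to each count and no scaling between samples, and this gave each library's depth, from 4.05 to 40.7 in reads divided by 1e+06. Kallisto's estimated counts need not be whole; 16.6% of recovered values between 0.2 and 50 were within 0.02 of a whole number. Because the offset weighs more in shallow libraries, changes of genes near 0 TPM depend on depth, and list medians include such genes. No fold change is given against a group in which a gene is listed at 0 TPM in every library.

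Genes at 1 TPM or more in at least 4 samples were tested (13387 genes). The main test was limma 3.58.1 in R 4.3.3, with the package data.table in version 1.17.8: 1 linear model with 8 group means on the log2 values without immunoglobulin genes, moderated with a mean-variance trend, and Benjamini-Hochberg adjustment over the genes of a comparison, with a threshold of 0.05. There were 14 comparisons of 2 groups and 3 interactions, each the change in MZ cells minus the change in FO cells. A gene "rose" or "fell" where its adjusted p was below 0.05. Replicate numbers were not used to pair samples. The labels do not name separate animals. These tests, the lists, the groups and the alternatives were chosen before the data were examined, except where said otherwise.

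The 32 gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation; counts of members are given over all genes tested and adjusted over the list alone. The lists were the plasma cell program, B cell identity, MHC class II presentation, marginal zone and follicular B cell markers, G1/S and DNA replication, G2/M and mitosis, D-type cyclins with CDK4/6, RB family and CDK inhibitors, the unfolded protein response, ER translocation, glycosylation and vesicle transport, and the ATF4 and amino acid response. Metabolic and growth lists were cholesterol biosynthesis, glycolysis, nuclear genes of oxidative phosphorylation, ribosome biogenesis, cytosolic ribosomal proteins and lysosome and autophagy. Signalling lists were p53 targets, FOXO, KLF2 and quiescence, the NF-kB and TLR response, the IL-4 and STAT response, the interferon response, the BCL2 family, immediate early and stress genes and mitochondrially encoded genes. Lists of cell types were germinal centre B cell markers, T cell markers, macrophage, monocyte and dendritic cell markers, NK cell and neutrophil markers, erythroid and platelet markers, B-1 cell markers, and immature and transitional B cell markers. Genes were named by a rule: 17 key genes, up to 4 members with the largest change past the threshold in each list called or described (if none passed, the member with the smallest p), and the 5 largest increases and 5 largest decreases among called genes with groups that do not overlap and a mean of at least 5 TPM in the higher group. This last part left out immunoglobulin and T cell receptor genes, predicted genes, pseudogenes, mitochondrial and ribosomal RNA genes. Other genes were chosen after their values were seen; these include heavy chain genes, second-list T cell genes, and genes named for their TPM in a further group.

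The key genes lie in GENCODE M21 (mm10) on chromosome 10 from 44437177 to 44528501 (Prdm1, minus strand), 11 from 5520659 to 5525893 (Xbp1, plus), 13 from 30749226 to 30766976 (Irf4, plus), 5 from 88519809 to 88527891 (Jchain, minus), 12 from 8771323 to 8793715 (Sdc1, plus), 16 from 11313812 to 11320074 (Tnfrsf17, plus), 1 from 171632403 to 171653035 (Slamf7, minus). Further ones are on 4 from 44524757 to 44710487 (Pax5, minus), 4 from 32238804 to 32586108 (Bach2, plus), 16 from 10480059 to 10528418 (Ciita, plus), 7 from 126408450 to 126414889 (Cd19, minus). The others are on 1 from 195136811 to 195176716 (Cr2, minus), 8 from 3681737 to 3694175 (Fcer2a, minus), 3 from 98013527 to 98150361 (Notch2, plus), 15 from 61985391 to 61990374 (Myc, plus), 7 from 135689784 to 135716361 (Mki67, minus) and 6 from 127125162 to 127152193 (Ccnd2, minus). Of the symbols tested, 12794 (95.6%) were found in that annotation.

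The immunoglobulin share is the TPM of immunoglobulin segments over the sum of a column, compared by a two-sided exact permutation test of the difference in means, adjusted over the 14 comparisons. The shared change was taken among genes called with a log2 change of at least 1 in divided cells, from fits of the 3 groups concerned, with binomial intervals that count genes as independent, beside values from simulated data in which only the fresh libraries were shared. The main test was tested on simulated data with planted changes: for MZ PD0332991 against fresh it recovered 19.7%, 53.7% and 91% of log2 changes of 0.5, 1 and 2 with 16 false calls among 13187 unchanged genes. Against divided MZ cells it recovered 4.55%, 40.3% and 88.1% with 4 false calls. These changes were planted in 66, 67 and 67 genes, none of them at the lowest counts. The real comparisons called 6427 and 3757 genes, so adjustment was stricter in the simulated data. The recovered shares and false calls therefore do not carry over to the real comparisons. A planted list of 25 genes changed by 0.5 was called (adjusted p = 3.13e-16 and 1.9e-22) and 0 of 31 unchanged lists were. Simulated genes varied independently, so this could not show false list calls that come from correlation between genes. Alternatives were the table with immunoglobulin genes, log2(TPM + 1) and a smaller pseudocount of 0.1, no filter, a filter of 5 TPM (10208 genes), only the compared samples, replicate number as a block, median-of-ratios scaling, and leaving out each library. Chosen after seeing the data were an offset scaled to depth, voom weights on recovered counts, leaving out 3 fresh libraries that stood apart, and median-of-ratios scaling for the lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made tables and figures. Sequence reads were not used here.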

Results

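Gene expression was measured in 34 libraries of mouse splenic B cells from B6.Blimp1GFP/+ mice, in 8 groups. In these mice green fluorescent protein (GFP) reports Prdm1, which encodes Blimp-1, the transcription factor that drives plasma cell formation. Follicular (FO) and marginal zone (MZ) B cells were sorted fresh from spleen (n = 5 libraries each), and 6 groups (n = 4 each) came from cultures with CpG, a Toll-like receptor 9 ligand, and the interleukins IL-4 and IL-5. FO cultures ran for 72 h and MZ cultures for 48 h. Divided GFP+ cells had gone through at least 4 divisions (FO) or 3 divisions (MZ). The other cultures held PD0332991, an inhibitor of the cell cycle kinases CDK4 and CDK6, or rapamycin, an inhibitor of mTOR, and undivided cells were sorted from them, GFP- for FO and GFP+ for MZ. Depth recovered from the deposited values was, in reads divided by 1e+06, 5.64 to 29 for fresh FO, 4.53 to 4.89 for divided FO, 5.8 to 7.59 for PD0332991-treated FO and 4.32 to 13.5 for rapamycin-treated FO libraries. It was 8.86 to 40.7 for fresh MZ, 4.33 to 7.7 for divided MZ, 4.05 to 7.09 for PD0332991-treated MZ and 5.46 to 8.34 for rapamycin-treated MZ libraries. Values after ± are standard errors for log2 changes and SDs for TPM and percentages. Because culture time went with the subset, and for inhibitor-treated cells the GFP gate did too, differences between FO and MZ cultures hold both. The labels do not say which libraries came from separate animals or cultures, so the p-values may measure technical spread.

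The libraries grouped by culture and subset. Xbp1, which drives the secretory program of plasma cells, stood at 173 ± 32.5 TPM in fresh FO cells and 207 ± 30.3 TPM in fresh MZ cells, and at 3090 ± 59.7 and 4290 ± 278 TPM in divided FO and MZ cells. It stood at 632 ± 10.5 and 615 ± 34.6 TPM in undivided FO cells under PD0332991 and rapamycin, and at 5080 ± 456 and 3310 ± 308 TPM in undivided MZ cells under the same drugs. The first principal component held 42.5% of the variance and ran from fresh FO (-83.61 to -78.22) and fresh MZ libraries (-75.27 to -63.43) through undivided FO (-12.75 to -4.34) and undivided MZ libraries (31.66 to 40.2) to divided MZ (64.94 to 68.61) and divided FO libraries (73.24 to 75.09). Within groups, libraries correlated at 0.916 to 0.966 over the genes tested. Among the fresh libraries, FO replicates 4 and 5 and MZ replicate 4 stood apart, on the fourth component at 62.14, 45.26 and 17.08 against -16.06 to -6.27 in the other FO and -41.18 to -28.74 in the other MZ libraries. Cr2, the complement receptor CD21, was at 124 and 110 TPM in these FO libraries against 274 to 306 TPM in the rest, and at 395 TPM in the MZ library against 756 to 861 TPM in the rest.

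**Figure D1:**
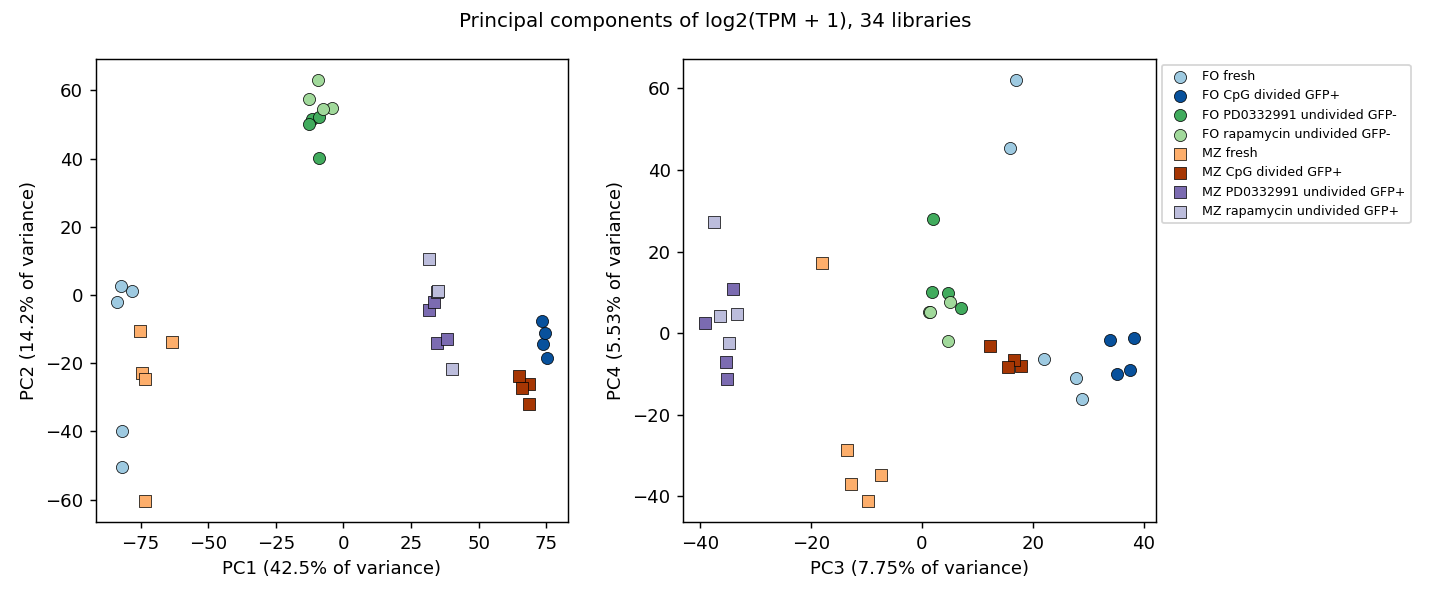
Principal components of log2(TPM + 1), one point per library. FO libraries are circles and MZ libraries are squares, and axes are labelled with the share of variance. Fresh and divided libraries lie at opposite ends of the first component (42.5%), undivided libraries lie between them, and 3 fresh libraries stand apart from the rest of their groups.

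**Figure D2:**
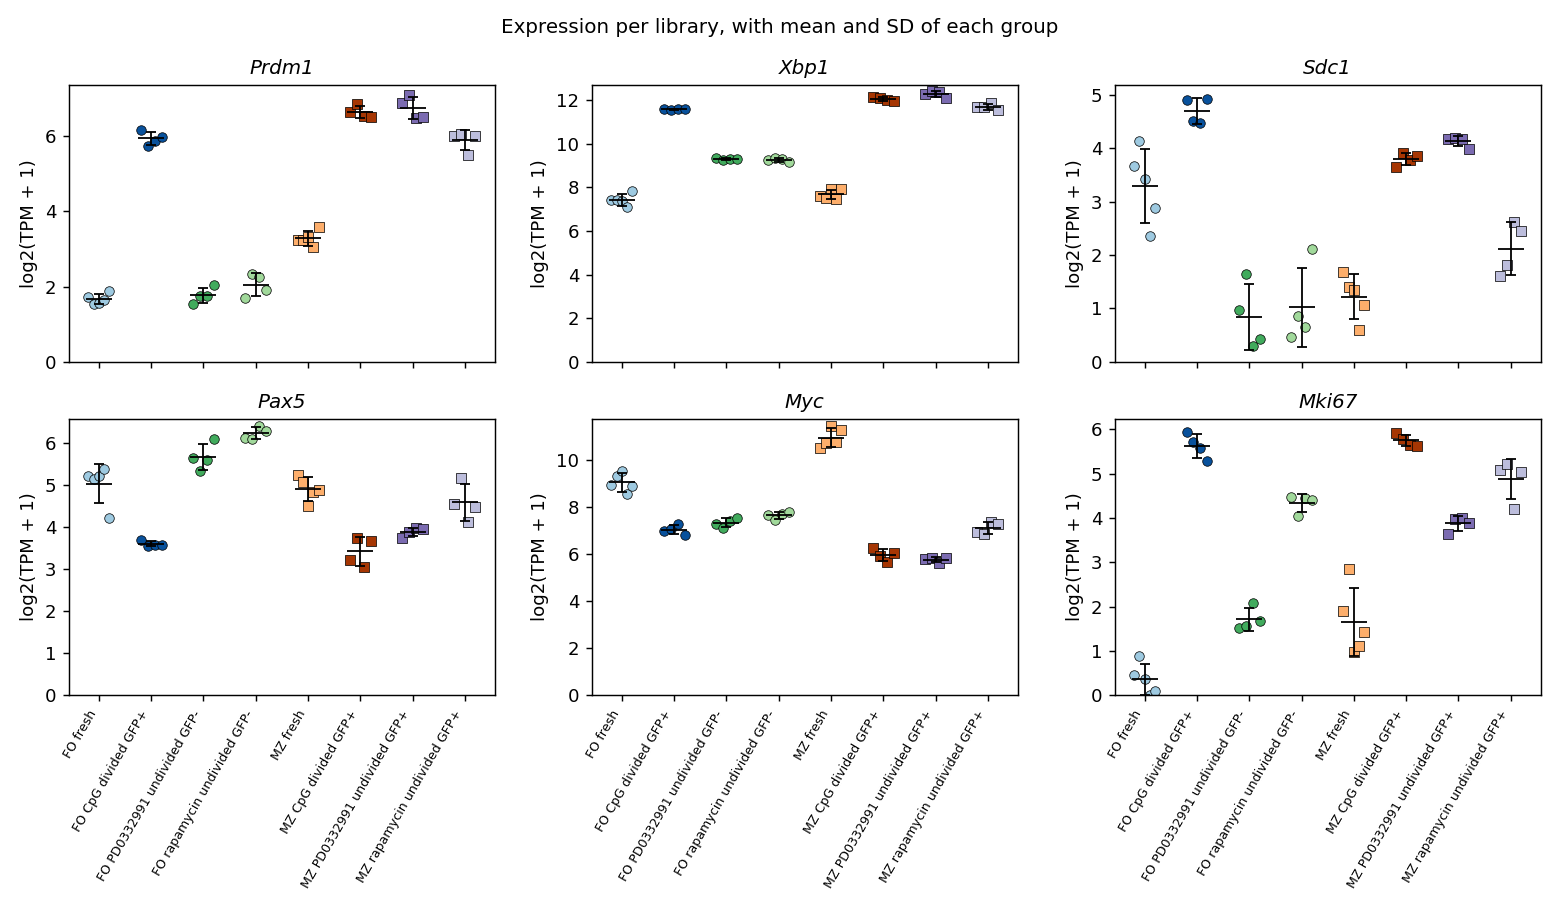
Levels of Prdm1, Xbp1, Sdc1, Pax5, Myc and Mki67 as log2(TPM + 1), one point per library with mean and SD, in 8 groups (n = 5 for fresh, n = 4 for cultured groups). Xbp1 is lowest in fresh cells (173 and 207 TPM on average) and highest in MZ cells under PD0332991 (5080 TPM), while Mki67 is lowest in fresh FO cells (0.319 TPM).

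The fresh subsets were compared to give the starting difference. S1pr3, a sphingosine phosphate receptor that holds cells in the marginal zone, was at 214 ± 79.2 TPM in fresh MZ cells and 6.15 TPM in fresh FO cells, a log2 change of 5.05 ± 0.21 (adjusted p = 4e-18). The tetraspanin Cd9 rose by 4.71 ± 0.15 (adjusted p = 4.1e-21) and the chemokine scavenger receptor Ackr3 by 6.63 ± 0.28 (adjusted p = 4e-18). Of 13 marginal zone markers 12 rose and 0 fell, with the same counts adjusted over the list alone (median 3.23, adjusted p = 8.86e-24). All 7 follicular markers measured fell, also adjusted over the list alone (median -1.55, adjusted p = 1.22e-13), among them Ccr7, which guides cells toward T cell zones (-1.84 ± 0.14), and the integrin chain Itgb7 (-2.04 ± 0.24). Fcer2a, the CD23 gene (-3.89 ± 0.29), and Cr2 (1.77 ± 0.38) were used to sort the subsets and are no finding. Each is in 1 of these lists; without the genes of the sort gates 11 of 12 marginal zone markers rose (adjusted p = 8.48e-24) and all 6 follicular markers fell (adjusted p = 8.71e-11), also adjusted over the list alone.

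Outside the marker lists, Myc, a driver of cell growth, was at 2070 ± 586 TPM against 548 ± 146 TPM (1.89 ± 0.15, adjusted p = 3.1e-11) in fresh MZ against fresh FO cells, and Prdm1 at 8.79 ± 1.37 against 2.18 ± 0.316 TPM (1.98 ± 0.16, adjusted p = 2.8e-11). Bach2, which represses Prdm1, fell by 2.17 on the log2 scale (SE 0.29). Of 33 mitosis genes 27 rose and 2 fell (30 and 2 adjusted over the list alone), and the median was 1.89 (adjusted p = 1.7e-16; adjusted p = 0.09 with an estimated correlation). Mki67, a marker of dividing cells, rose by 3.68 ± 0.59 yet reached only 2.58 ± 2.18 TPM. Of 23 plasma cell genes 9 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.0191; adjusted p = 0.09 with an estimated correlation; adjusted p = 0.0814 without Prdm1). Derl3, a degradation factor of the endoplasmic reticulum (ER), rose by 2.05 ± 0.24, and the surface proteoglycan Sdc1 fell by 2.80 on the log2 scale (SE 0.49). The unfolded protein response list had 10 of 26 up and 0 down (10 and 1 adjusted over the list alone), with the disulfide isomerase Pdia4 up 2.41 ± 0.14 (adjusted p = 0.00848; adjusted p = 0.299 with an estimated correlation). Cholesterol genes went the other way, with 8 of 25 down and 1 up, or 9 and 1 adjusted over the list alone (adjusted p = 2.05e-05; adjusted p = 0.09 with an estimated correlation). The LDL receptor Ldlr (-1.65 ± 0.22) and the squalene epoxidase Sqle (-1.03 ± 0.11) were among them. Some markers of other cells were higher in fresh MZ libraries: Prf1 and Gzma, of killer lymphocytes, by 2.96 ± 0.32 and 5.26 ± 1.18, and Cd8b1, of T cells, by 2.76 ± 0.48. The killer and neutrophil list (4 of 11 up, adjusted p = 0.146) and the T cell list (3 of 12 up, adjusted p = 0.28) were not called. In all, 2515 of 13387 genes passed, 1785 up and 730 down (71% up; 59.1% after median-of-ratios scaling). A fit of only the fresh libraries called 1265 genes, and without the 3 libraries that stand apart 2705 were called.

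Divided GFP+ FO cells were compared with fresh FO cells to show what culture with CpG, IL-4 and IL-5 changed in cells that had divided and expressed the reporter. The cells had taken on the transcripts of antibody secretion and of division: Xbp1 rose by 4.18 ± 0.11 (adjusted p = 5.9e-24), Derl3 by 5.25 ± 0.25, and Tnfrsf17, the survival receptor BCMA, by 5.70 ± 0.82 to 10.7 TPM. Prdm1 rose by 4.80 ± 0.17, but its reporter was the sort gate, so its rise is no finding. Of 23 plasma cell genes 20 rose and 0 fell, or 20 and 1 adjusted over the list alone (median 3.49, adjusted p = 3.05e-09). Of 26 unfolded protein response genes 24 rose (25 adjusted over the list alone), such as the ER chaperone partners Sdf2l1 (3.76 ± 0.17) and Creld2 (3.70 ± 0.15). In the list of ER translocation, glycosylation and vesicle transport 35 of 37 rose, also adjusted over the list alone, such as the cargo receptor Lman1 (3.92 ± 0.12) and the coat protein Sec24d (5.55 ± 0.3). The adjusted p was 1.14e-13 and 2.67e-16 for these lists. All 33 mitosis genes rose, also adjusted over the list alone (median 5.42, adjusted p = 2.05e-21), with Mki67 going from 0.319 to 49.2 ± 9.41 TPM (8.29 ± 0.63). In the DNA replication list 32 of 35 rose and 1 fell (34 and 1 adjusted over the list alone, adjusted p = 7.56e-16), with the ribonucleotide reductase subunit Rrm2 up 6.55 ± 0.2.

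The B cell program fell in the same cells. All 22 B cell identity genes fell, also adjusted over the list alone (median -2.10, adjusted p = 4.68e-16), among them Cd72, an inhibitory coreceptor (-5.07 ± 0.17), and Pax5, the factor that keeps B cell identity (-1.51 ± 0.2). All 10 MHC class II presentation genes fell, again adjusted over the list alone as well, such as H2-Oa (-4.59 ± 0.18) and the class II transactivator Ciita (-2.69 ± 0.23; list adjusted p = 1.95e-11). Sell, the homing receptor L-selectin, went from 1160 ± 111 to 10.7 ± 3.33 TPM (-6.80 ± 0.19). Of 16 quiescence genes 12 fell and 0 rose (13 and 0 adjusted over the list alone, adjusted p = 2.44e-11), with Tsc22d3, a target of glucocorticoids and FOXO factors, at -6.01 ± 0.14. Immediate early genes were far lower than in freshly sorted cells: Fos went from 764 to 0.451 TPM (-11.19 ± 0.63) and Nr4a1 from 1420 to 1.75 TPM (-9.56 ± 0.26). In all 15 of 17 list members fell and 1 rose, also adjusted over the list alone (adjusted p = 5.94e-11). Interferon response genes fell in 20 of 26 cases and rose in 3, with the same counts adjusted over the list alone (median -2.69, adjusted p = 2.51e-07). In the NF-kB and Toll-like receptor list 11 of 21 fell and 7 rose, also adjusted over the list alone; the median was -1.17 and the mean 0.04, while the test called the list down (adjusted p = 0.0137; adjusted p = 0.181 with an estimated correlation). Its members up the most were the cytokines Il6 (7.65 ± 0.83) and Il10 (5.17 ± 0.7) and the survival gene Bcl2l1 (4.27 ± 0.22).

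Metabolic genes rose broadly in divided FO cells. The amino acid response list had 22 of 27 up and 3 down, also adjusted over the list alone (adjusted p = 2.31e-08), with asparagine synthetase Asns up 8.02 ± 0.54. All 25 cholesterol genes rose, also adjusted over the list alone (adjusted p = 5.16e-11), and 14 of 17 glycolysis genes rose with 0 down, the same adjusted over the list alone (adjusted p = 4.51e-09), with the lactate exporter Slc16a3 at 218 TPM against 0.364 TPM. Of 32 ribosome biogenesis genes 27 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.71e-05), while Myc itself fell by 2.02 on the log2 scale (SE 0.16). The nuclear genes of oxidative phosphorylation (53 of 60 up, 54 adjusted over the list alone; adjusted p = 6.4e-10) and the ribosomal proteins (62 of 75 up, 63 adjusted over the list alone; adjusted p = 2.28e-06) were called with the preset correlation. Their adjusted p = 0.293 and adjusted p = 0.608 with an estimated correlation. The IL-4 response list had 8 of 10 up and 1 down, also adjusted over the list alone (adjusted p = 0.00238), with the cytokine signalling inhibitor Cish up 6.33 ± 0.38. The 5 largest increases were in Tmed6, a vesicle transport protein (0.118 to 360 ± 59.2 TPM, 11.13 ± 0.35), Hid1, Klrg2, Cldn7 and Htr7. Among T cell markers 3 of 12 rose and 3 fell, with Thy1 up 6.95 ± 0.67, and the list was not called (adjusted p = 0.753). In all, 8191 genes passed, 4865 up and 3326 down (59.4% up; 48.6% after median-of-ratios scaling, which moved the median of all genes from 0.21 to -0.08).

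Divided GFP+ MZ cells were compared with fresh MZ cells in the same way. Xbp1 rose by 4.46 ± 0.11 (adjusted p = 1.6e-24), Sdc1 by 3.43 ± 0.52 to 13 ± 1.04 TPM, and the ER foldase Fkbp11 by 5.60 ± 0.21. Plasma cell genes rose in 18 of 23 cases and fell in 1, also adjusted over the list alone (median 2.51, adjusted p = 1.09e-09). All 26 unfolded protein response genes and all 37 ER transport genes rose, also adjusted over the list alone (adjusted p = 1.46e-17 and 3.33e-23), with the ER stress factor Manf up 4.05 ± 0.17. All 33 mitosis genes rose, also adjusted over the list alone (median 3.82, adjusted p = 6.32e-20), with Mki67 up 4.79 ± 0.63 to 52.9 ± 5.1 TPM, and 34 of 35 DNA replication genes rose, also adjusted over the list alone (adjusted p = 1.03e-17). The list of D-type cyclins, CDK4/6, RB family and CDK inhibitors had 8 of 14 up and 0 down, also adjusted over the list alone (adjusted p = 0.00253), with cyclin D2 Ccnd2 up 3.73 ± 0.12 and the CDK inhibitor Cdkn1a up 3.36 ± 0.29.

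Marginal zone identity fell in divided MZ cells: 11 of 13 markers fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 3.66e-05), with S1pr3 down to 5.72 TPM (-5.07 ± 0.23) and the Notch target Hes1 to 7.88 TPM (-5.13 ± 0.35). B cell identity fell in 20 of 22 genes (21 adjusted over the list alone) and MHC class II in all 10 measured, also adjusted over the list alone, with Cd72 at -5.66 ± 0.17 and H2-Oa at -5.15 ± 0.18 (adjusted p = 3.46e-15 and 1.66e-09). Myc fell from 2070 ± 586 to 63 ± 11.3 TPM (-4.92 ± 0.16). Interferon genes fell in 17 of 26 cases and rose in 5 (18 and 5 adjusted over the list alone, adjusted p = 0.00217), and NF-kB genes fell in 14 of 21 and rose in 3, also adjusted over the list alone (adjusted p = 7.75e-06). Quiescence genes fell in 12 of 16, the same adjusted over the list alone (adjusted p = 4.87e-10), with Btg1, which restrains division, at -5.85 ± 0.12. Cholesterol genes rose in 24 of 25 cases (adjusted p = 3.31e-13), glycolysis genes in 14 of 17 with 1 down (adjusted p = 3.89e-08). Amino acid response genes rose in 22 of 27 with 2 down (adjusted p = 1.04e-08), each with the same counts adjusted over the list alone. The largest increase was in the stress factor Nupr1, from 0.0896 ± 0.148 to 275 ± 3.32 TPM (11.57 ± 0.51), and the largest decreases were in Plaur, the urokinase receptor (-10.74 ± 0.65), and Nr4a1 (-10.46 ± 0.26). In all, 7539 genes passed, 3947 up and 3592 down. Without fresh MZ replicate 4 and the FO libraries that stand apart 8089 were called.

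Divided MZ cells were set against divided FO cells to show how plasma cells of the 2 origins differ. Interferon response genes were higher in MZ cells: Ifi27l2a was at 1060 ± 156 against 98.6 ± 25.4 TPM (3.50 ± 0.22, adjusted p = 9.9e-13). Of 26 list members 14 rose and 0 fell (15 and 0 adjusted over the list alone, median 1.00, adjusted p = 3.58e-21). The antiviral genes Usp18 (2.45 ± 0.32) and Oas2 (3.59 ± 0.56) were among them; Oas2 was at 0.73 and not called on log2(TPM + 1). Origin markers still differed, with 5 of 13 marginal zone markers up and 0 down (7 and 0 adjusted over the list alone, adjusted p = 3.6e-08), such as Cd9 (1.25 ± 0.16). Of 7 follicular markers 4 fell (5 adjusted over the list alone, adjusted p = 5.87e-10), such as Ccr7 (-1.60 ± 0.16). Of the plasma cell genes 3 of 23 rose and 2 fell (9 and 4 adjusted over the list alone, adjusted p = 0.00985), with Tnfrsf17 at -2.85 ± 0.86 and Prdm1 at 0.76 ± 0.18. Without Prdm1, whose reporter was the gate of both groups, the list had adjusted p = 0.0307, and adjusted p = 0.0933 with an estimated correlation. The unfolded protein response rose in 5 of 26 genes (11 up and 1 down adjusted over the list alone, adjusted p = 9.22e-08), such as the chaperone Dnajb9 (0.79 ± 0.16). Lower in MZ cells were 10 of 32 ribosome biogenesis genes (13 adjusted over the list alone, adjusted p = 1.91e-09), such as nucleolin Ncl (-0.62 ± 0.13). Also lower were 8 of 21 NF-kB genes (9 down and 1 up adjusted over the list alone, adjusted p = 0.000145), such as the cytokine Tnf (-2.11 ± 0.43), and 6 of 17 glycolysis genes (10 adjusted over the list alone, adjusted p = 1.63e-06). Cholesterol genes fell in 6 of 25 cases (10 adjusted over the list alone, adjusted p = 1.11e-05). Aicda, the deaminase of antibody diversification, was at 8.6 against 44.3 TPM (-2.36 ± 0.6). Wnt10a, a Wnt ligand, and Parva, an adhesion adaptor, were among the largest decreases (-6.17 ± 0.55 and -6.41 ± 0.48). The call of Tnfrsf17 was lost with no filter and that of Tnf with voom weights. In all, 931 genes passed, 372 up and 559 down, and a fit of only these 8 libraries called 1891.

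The change from fresh to divided cells differed between the subsets where the interaction (change in MZ minus change in FO) was tested. Larger and smaller refer to the sign of this difference, so a smaller change can be a deeper fall in MZ cells. Of 33 mitosis genes 26 had a smaller change in MZ cells and 1 a larger one (27 and 2 adjusted over the list alone), and the list was called (adjusted p = 9.42e-13; adjusted p = 0.11 with an estimated correlation). Mki67 had the difference -3.50 ± 0.89, from a higher fresh level in MZ cells. Marginal zone markers differed in 9 of 13 cases (10 adjusted over the list alone, adjusted p = 2.6e-13), such as S1pr3 (-4.02 ± 0.32). Interferon genes had 8 of 26 positive differences and 0 negative (9 and 0 adjusted over the list alone, adjusted p = 1.76e-07). Most genes of that list fell in both subsets, so a positive difference can be a weaker fall in MZ cells. Of 21 NF-kB genes 12 had negative and 2 positive differences (13 and 2 adjusted over the list alone, adjusted p = 1.49e-05). More genes of that list fell than rose in both subsets. Ribosome biogenesis genes had 15 of 32 negative differences (23 adjusted over the list alone, adjusted p = 9.44e-09). In the plasma cell list 8 of 23 had smaller and 3 larger changes (8 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.552). Myc had the difference -2.91 and Bach2 1.45. The interaction called 1788 genes, 461 larger and 1327 smaller in MZ cells (25.8% larger; 38.9% after median-of-ratios scaling, which moved the median of all genes from -0.16 to 0). A fit of only the compared libraries called 1161 and did not call Mki67.

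Undivided GFP- FO cells under PD0332991 or rapamycin were compared with fresh FO cells to show changes without division and without reporter expression. No undivided group without a drug was measured, so effects of culture and drug cannot be told apart here. Xbp1 rose by 1.89 ± 0.11 and 1.80 ± 0.11 (adjusted p = 6.9e-15 and 1.8e-14). Irf4, a factor needed for plasma cells, fell by 2.37 and 2.54 on the log2 scale (SE 0.38 each) and Sdc1 by 3.66 and 3.28 on the log2 scale (SE 0.52 each). Irf4 varied among fresh FO libraries (122 ± 88.9 TPM). In the plasma cell list 13 of 23 rose and 4 fell under PD0332991 and 11 and 4 under rapamycin, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.192 and 0.381). Pax5 rose from 33.1 ± 8.96 TPM to 74.7 ± 7.66 TPM under rapamycin (1.18 ± 0.2), and Ciita rose by 1.02 ± 0.23 and 1.24 ± 0.23 under PD0332991 and rapamycin. The MHC class II list, which holds Ciita, went the other way: of 10 genes 1 rose and 5 fell under each drug (1 and 8, and 1 and 6, adjusted over the list alone), with medians of -0.38 and -0.51. It had adjusted p = 0.00267 and 0.00565; adjusted p = 0.279 and adjusted p = 0.381 with an estimated correlation, and under rapamycin adjusted p = 0.0988 without the 3 fresh libraries that stand apart. Of 22 B cell identity genes 13 fell and 6 rose under PD0332991, and 11 and 6 under rapamycin, also adjusted over the list alone, with the inhibitory receptor Btla at -2.73 ± 0.24 and -2.65 ± 0.24. The list had adjusted p = 0.000166 and 0.00219; adjusted p = 0.0981 and adjusted p = 0.155 with an estimated correlation.

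IL-4 response genes rose in undivided FO cells. Il4i1, an amino acid oxidase induced by IL-4, reached 2120 ± 130 TPM under PD0332991 and 2160 ± 97.9 TPM under rapamycin against 83.9 TPM in fresh cells. The list had 9 of 10 up and 0 down under PD0332991 (median 4.72, adjusted p = 1.46e-11) and 9 up and 1 down under rapamycin (median 4.58, adjusted p = 1.22e-09), with the same counts adjusted over the list alone. The chemokine Ccl22 rose by 9.15 ± 0.75 and 9.83 ± 0.75 and Cish by 7.43 ± 0.38 and 7.59 ± 0.38. Of 25 cholesterol genes 22 rose and 0 fell in each, also adjusted over the list alone (adjusted p = 4.87e-11 and 1.85e-12), with Sqle up 2.77 ± 0.12 and 3.01 ± 0.12. Ribosomal proteins rose in 70 of 75 cases under PD0332991 (71 adjusted over the list alone, adjusted p = 2.11e-16) and 61 under rapamycin (63 adjusted over the list alone, adjusted p = 4.64e-09); their adjusted p = 0.318 and adjusted p = 0.59 with an estimated correlation. Immediate early genes fell in 14 and 13 of 17 cases and rose in 2, also adjusted over the list alone (adjusted p = 1.74e-16 and 2.66e-17), with Fos at -9.27 ± 0.63 and -9.82 ± 0.63.

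Cell cycle genes rose in these undivided FO cells too. Ccnd2 went from 11.9 ± 1.26 to 109 ± 10.7 TPM under PD0332991 (3.19 ± 0.12) and 101 ± 12.8 TPM under rapamycin (3.04 ± 0.12). Mki67 reached 2.33 ± 0.646 TPM under PD0332991 (3.88 ± 0.63) and 19.4 ± 2.69 TPM under rapamycin (6.91 ± 0.63). Of 33 mitosis genes 29 rose and 1 fell under PD0332991 (30 and 1 adjusted over the list alone, median 2.21, adjusted p = 3.21e-10; adjusted p = 0.179 with an estimated correlation). All 33 rose under rapamycin, also adjusted over the list alone (median 4.35, adjusted p = 1.72e-28). DNA replication genes rose in 23 of 35 cases and fell in 4 under PD0332991 (24 and 4 adjusted over the list alone, adjusted p = 0.000537; adjusted p = 0.206 with an estimated correlation). Under rapamycin they rose in 30 and fell in 1, also adjusted over the list alone (adjusted p = 4.68e-14). T cell transcripts rose in the same libraries: 11 of 12 markers rose and 0 fell under each drug, also adjusted over the list alone. Cd3e was at 17.3 ± 4.84 and 11.6 ± 2.88 TPM against 0.0717 TPM in fresh cells, and Thy1 rose by 8.01 ± 0.67 and 7.72 ± 0.67. That list was called (median 4.82 and 4.07, adjusted p = 0.000166 and 0.00151; adjusted p = 0.179 and adjusted p = 0.283 with an estimated correlation). The killer lymphocyte gene Gzmb rose by 8.44 ± 1.21 to 15.6 ± 4.89 TPM under PD0332991. In all, 5980 genes passed under PD0332991, 4137 up and 1843 down (69.2% up; 49.8% after median-of-ratios scaling, with the median of all genes going from 0.26 to -0.01). Under rapamycin 5931 passed, 4264 up and 1667 down (71.9% up; 49.1% after that scaling, median from 0.33 to 0).

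Undivided GFP+ MZ cells under the drugs were compared with fresh MZ cells to show changes in cells that expressed the reporter without dividing. Under PD0332991 Xbp1 rose by 4.71 ± 0.11 (adjusted p = 9.6e-25), Sdc1 by 3.79 ± 0.52 to 16.6 ± 1.09 TPM and Derl3 by 4.64 ± 0.25 to 541 ± 126 TPM. Under rapamycin Xbp1 rose by 4.07 ± 0.11, Derl3 by 4.41 ± 0.25 and Sdc1 by 1.46 to 3.54 ± 1.49 TPM. Prdm1 was again the sort gate (107 ± 22.3 and 59.1 ± 10.1 TPM). Because this gate selected cells that expressed a driver of plasma cell formation, the rise of plasma cell genes can come in part from the sort. It does not tell how many undivided MZ cells reached that state. In the plasma cell list 19 of 23 rose and 0 fell under PD0332991, also adjusted over the list alone (median 2.89, adjusted p = 2.71e-15), and 16 rose and 3 fell under rapamycin (17 and 3 adjusted over the list alone, median 1.76, adjusted p = 3.14e-08). All 26 unfolded protein response genes rose under PD0332991, also adjusted over the list alone (adjusted p = 3.66e-23), and 24 under rapamycin (26 adjusted over the list alone, adjusted p = 4.45e-16), with Manf up 3.94 ± 0.17 and 3.83 ± 0.17. ER transport genes rose in 36 and 33 of 37 cases, also adjusted over the list alone (adjusted p = 5.89e-25 and 4.45e-16). The B cell program fell, with 19 and 16 of 22 identity genes down and 1 up (19 and 17 down adjusted over the list alone, adjusted p = 9.87e-11 and 3.62e-08) and Cd72 at -2.85 ± 0.17 and -2.38 ± 0.17. Bach2 went against the list, up 2.29 ± 0.31 and 2.53 ± 0.31.

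Division genes rose in undivided MZ cells as well, though less under PD0332991. All 33 mitosis genes rose under both drugs, also adjusted over the list alone, with a median of 2.22 under PD0332991 (adjusted p = 2.71e-15; adjusted p = 0.0597 with an estimated correlation) and 3.89 under rapamycin (adjusted p = 1.54e-27). Rrm2 was at 309 and 779 TPM against 35.3 TPM in fresh and 996 TPM in divided MZ cells, and Ccnd2 rose by 4.35 ± 0.12 and 4.01 ± 0.12. DNA replication genes rose in 29 and 34 of 35 cases and fell in 1 (30 and 34 up adjusted over the list alone, adjusted p = 2.58e-08 and 3.07e-22). The list of D-type cyclins, CDK4/6, RB family and CDK inhibitors had 9 of 14 up under both and 2 and 1 down, also adjusted over the list alone, with the CDK inhibitor Cdkn2b up 4.42 ± 0.59 and 4.81 ± 0.59 (adjusted p = 0.00678 and 1.32e-05). Myc fell to 53.9 ± 4.11 TPM under PD0332991 (-5.14 ± 0.16), and 17 of 32 ribosome biogenesis genes fell and 2 rose, also adjusted over the list alone, with nucleophosmin Npm1 at -1.10 ± 0.13 (adjusted p = 7.58e-05; adjusted p = 0.0681 with an estimated correlation). All 10 IL-4 response genes rose under both, also adjusted over the list alone (adjusted p = 2.71e-10 and 2.04e-10), with Il4i1 up 4.16 ± 0.19 under PD0332991. Nupr1 rose most, by 11.21 ± 0.51 and 12.24 ± 0.51, and Hnf1b, a homeobox factor, by 10.43 ± 0.46 and 10.93 ± 0.46. T cell markers rose in 2 of 12 cases and fell in 2 under PD0332991 (adjusted p = 0.95) and rose in 2 and fell in 5 under rapamycin (adjusted p = 0.387). In all, 6427 genes passed under PD0332991, 3409 up and 3018 down, and 6214 under rapamycin, 3402 up and 2812 down. Of 1403 genes below 1 TPM on average in both groups under PD0332991 244 were called, 195 of them up. With an offset scaled to each library's depth 206 were called, only 81 of them up, and 129 of the 244 kept their call.

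The changes under each drug differed between MZ and FO cells in the interaction test, with the gate and culture time differing as well. Larger and smaller again refer to the sign of the change in MZ minus that in FO cells. Sdc1 had a change larger in MZ cells by 7.45 ± 0.73 under PD0332991 (adjusted p = 5e-09) and 4.73 ± 0.73 under rapamycin, and Xbp1 by 2.81 and 2.28. Among plasma cell genes 20 of 23 had larger changes and 0 smaller under PD0332991, also adjusted over the list alone (median 2.17, adjusted p = 3.06e-29), and 14 and 0 under rapamycin (14 and 1 adjusted over the list alone, median 1.29, adjusted p = 6.6e-16). The unfolded protein response had 20 of 26 larger under PD0332991 (21 adjusted over the list alone) and 18 larger and 1 smaller under rapamycin (19 and 1 adjusted over the list alone), with Creld2 at 3.29 ± 0.22 and 3.27 ± 0.22 (adjusted p = 6.43e-35 and 3.12e-27). ER transport genes had 34 and 31 of 37 larger (35 and 32 adjusted over the list alone, adjusted p = 4.19e-40 and 8.06e-28). Under PD0332991 30 of 32 ribosome biogenesis genes had negative differences (31 adjusted over the list alone, adjusted p = 6.63e-16). Against fresh cells that list had a median of 0.57 in FO and -0.46 in MZ cells, so the changes went opposite ways. T cell markers had negative differences too, 11 of 12 under PD0332991 (12 adjusted over the list alone), with Cd3e at -7.78 ± 1.3. Under rapamycin 10 were negative (12 adjusted over the list alone). The T cell list had adjusted p = 5.6e-06 and 2.11e-06; adjusted p = 0.0843 and adjusted p = 0.0624 with an estimated correlation. The interactions called 2854 genes under PD0332991, 961 larger and 1893 smaller (33.7% larger; 52.8% after median-of-ratios scaling, which moved the median of all genes from -0.23 to -0.01). Under rapamycin there were 2673, 971 larger and 1702 smaller (36.3% larger; 54.3% after that scaling, median from -0.28 to -0.04). A fit of only the compared libraries called 1603 genes for rapamycin.

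Undivided FO cells were then set against divided FO cells, which differ in drug, division and gate at once. Sell was at 1010 ± 141 TPM under PD0332991 and 1030 ± 98.7 TPM under rapamycin, against 10.7 ± 3.33 TPM in divided cells (6.60 ± 0.2 and 6.57 ± 0.2). Of 23 plasma cell genes 21 and 20 were lower and 0 higher (21 and 21 adjusted over the list alone, adjusted p = 1.06e-16 and 3.2e-17), with Sdc1 at -5.19 ± 0.55 and -4.81 ± 0.55. B cell identity genes were higher in 19 and 22 of 22 cases (20 and 22 adjusted over the list alone, adjusted p = 2.09e-15 and 4.82e-16). MHC class II genes were higher in all 10 cases, also adjusted over the list alone (adjusted p = 1.05e-13 and 2.88e-13), with Ciita up 3.71 ± 0.25 and 3.93 ± 0.25. All 33 mitosis genes were lower under PD0332991, also adjusted over the list alone (median -3.37, adjusted p = 3.16e-27). Under rapamycin 24 were lower (28 adjusted over the list alone, median -1.35, adjusted p = 1.08e-09; adjusted p = 0.156 with an estimated correlation). Glycolysis genes were lower in 15 of 17 cases under both (adjusted p = 1.63e-13 and 3.72e-15; 1 gene was higher under rapamycin adjusted over the list alone), such as triose phosphate isomerase Tpi1 (-3.08 ± 0.16 and -3.05 ± 0.16). Amino acid response genes were lower in 22 and 23 of 27 cases and higher in 1 and 2 (22 and 23 lower and 2 higher adjusted over the list alone, adjusted p = 1.06e-09 and 2.94e-14). Interferon genes were higher in 20 and 16 of 26 cases and lower in 1 and 3 (20 and 17 higher adjusted over the list alone, adjusted p = 1.02e-09 and 5.05e-05). T cell markers were also higher in 9 of 12 cases under both, adjusted over the list alone too, with Tcf7 up 6.95 ± 0.9 and 6.26 ± 0.9 (adjusted p = 7.66e-05 and 0.000748; adjusted p = 0.105 and adjusted p = 0.173 with an estimated correlation). In all, 5709 genes passed under PD0332991, 2921 up and 2788 down, and 6207 under rapamycin, 3371 up and 2836 down.

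Undivided GFP+ MZ cells and divided GFP+ MZ cells share the gate, so this comparison is closest to one of division and drug alone. Under PD0332991 the plasma cell list was not called: 7 of 23 rose and 2 fell, also adjusted over the list alone (median 0.10, adjusted p = 0.185), with Derl3 up 1.02 ± 0.26 and Fkbp11 at -0.99 ± 0.22. The unfolded protein response had 4 of 26 up and 2 down, also adjusted over the list alone (adjusted p = 0.828). Under rapamycin 14 plasma cell genes fell and 2 rose (16 and 2 adjusted over the list alone, median -0.77, adjusted p = 6.94e-06), with Sdc1 at -1.98 ± 0.55, and 15 unfolded protein response genes fell (19 adjusted over the list alone, adjusted p = 2.1e-08). ER transport genes fell in 20 of 37 cases under PD0332991 (24 adjusted over the list alone, adjusted p = 7.39e-08) and 33 under rapamycin, also adjusted over the list alone (adjusted p = 5.82e-24), with the retrieval receptor Kdelr2 at -1.06 ± 0.16 and -1.87 ± 0.16. B cell identity genes rose in 15 and 17 of 22 cases (17 and 17 adjusted over the list alone, adjusted p = 3.67e-13 and 9.15e-16). MHC class II genes rose in all 10 cases, also adjusted over the list alone (adjusted p = 1.06e-15 and 9.15e-16), with H2-Oa up 3.71 ± 0.19 and 3.93 ± 0.19. NF-kB genes rose in 15 and 17 of 21 cases (18 up, and 18 up and 1 down, adjusted over the list alone; adjusted p = 3.77e-16 and 1.23e-16), such as Cd83, an activation marker (3.04 ± 0.16 and 3.67 ± 0.16).

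Division genes separated the drugs in this comparison. Under PD0332991 30 of 33 mitosis genes fell (31 adjusted over the list alone, median -1.55, adjusted p = 1.25e-17) and 33 of 35 DNA replication genes fell (34 adjusted over the list alone, adjusted p = 2.76e-22), with Rrm2 at -1.71 ± 0.21. Under rapamycin 2 mitosis genes rose, also adjusted over the list alone (median 0.10, adjusted p = 0.383), and 2 DNA replication genes rose and 4 fell (2 and 2 adjusted over the list alone, adjusted p = 0.314); the thymidine kinase Tk1 rose by 0.72 ± 0.16. Glycolysis genes fell in 15 of 17 cases under both (adjusted p = 9.47e-18 and 7.55e-20; under PD0332991 1 gene rose adjusted over the list alone). Lactate dehydrogenase Ldha was at 3050 ± 630 TPM in divided cells and 744 ± 58.9 and 701 ± 70.6 TPM in undivided cells. Lysosome genes rose in 14 of 25 cases under PD0332991 (16 adjusted over the list alone, adjusted p = 3.71e-09), with the protease Ctsa up 1.95 ± 0.1, while under rapamycin 7 rose and 4 fell (7 and 5 adjusted over the list alone, adjusted p = 0.314). Ribosome biogenesis genes fell in 23 and 14 of 32 cases (26 and 16 adjusted over the list alone, adjusted p = 3.84e-12 and 2.67e-06). T cell markers under PD0332991 had 2 of 12 up, Tcf7 (2.72 ± 0.9) and Lck, a kinase that B cells here also expressed (2.00 ± 0.23), the same adjusted over the list alone (adjusted p = 0.0398; adjusted p = 0.373 with an estimated correlation). On log2(TPM + 1) Tcf7 was at 0.60 and not called, and neither was the list (adjusted p = 0.109). In all, 3757 genes passed under PD0332991, 1881 up and 1876 down, and 3737 under rapamycin, 2079 up and 1658 down.

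**Figure D3:**
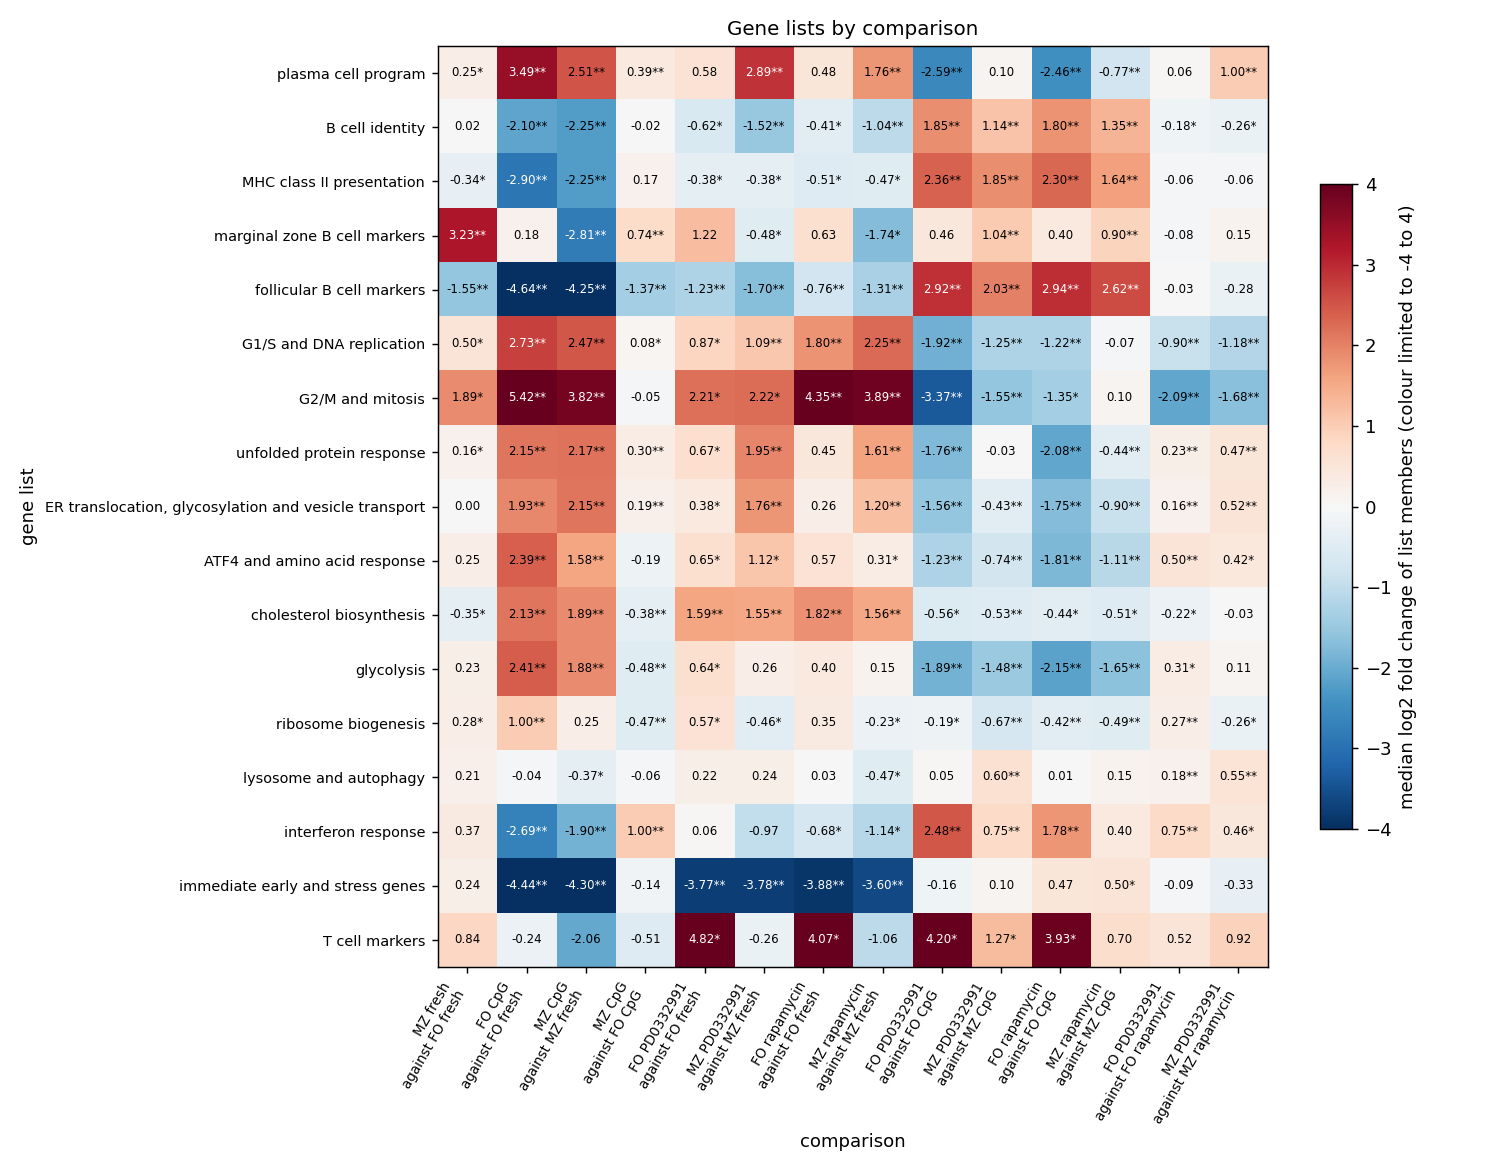
Median log2 fold change of the members of 17 gene lists (y axis) in 14 comparisons (x axis), with colour limited to -4 to 4. A double asterisk marks lists called with both the preset and an estimated correlation, a single one lists called with the preset only; the plasma cell program is at 2.89 in MZ cells under PD0332991 against fresh and at -2.59 in FO cells under PD0332991 against divided cells.

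PD0332991 was set directly against rapamycin in undivided FO cells. Mitosis genes were lower under PD0332991: Mki67 was at 2.33 ± 0.646 against 19.4 ± 2.69 TPM (-3.03 ± 0.66, adjusted p = 0.0053) and Tk1 at 20.8 ± 2.96 against 78.5 ± 11.4 TPM (-1.85 ± 0.16). Cdkn3, a cell cycle phosphatase, was at 3.57 ± 1.19 against 42.4 ± 3.48 TPM (-3.50 ± 0.41). Of 33 mitosis genes 30 fell (33 adjusted over the list alone, median -2.09, adjusted p = 6.46e-75), and of 35 DNA replication genes 21 fell (33 adjusted over the list alone, median -0.90, adjusted p = 2.54e-41). The list of D-type cyclins, CDK4/6, RB family and CDK inhibitors had 3 of 14 down (5 adjusted over the list alone, adjusted p = 0.00155), the CDK inhibitors Cdkn2b (-2.28 ± 0.62) and Cdkn2c (-1.71 ± 0.2) and the pocket protein Rbl1 (-0.82 ± 0.18). Higher under PD0332991 were 7 of 27 amino acid response genes (14 adjusted over the list alone, adjusted p = 7.88e-14), such as Trib3 (1.61 ± 0.31), and Ly6a, the surface protein Sca-1 (646 ± 66.5 against 151 ± 5.2 TPM, 2.15 ± 0.14, adjusted p = 5.4e-12). Interferon genes rose in 2 of 26 cases, Zbp1 and Bst2 (8 adjusted over the list alone, adjusted p = 1.17e-11). In all, 388 genes passed, 112 up and 276 down. Cdkn2b was at -0.54 and not called on log2(TPM + 1). A fit of only these libraries called 940, a fit with replicate number as a block 760, and without FO PD0332991 replicate 6 the count was 257.

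In undivided MZ cells PD0332991 left more of the plasma cell program and less of the division program than rapamycin. Sdc1 was at 16.6 ± 1.09 against 3.54 ± 1.49 TPM (2.33 ± 0.55, adjusted p = 0.0033). Ly6c2, a surface protein of plasma cells and other lymphocytes, was at 81.9 ± 19.3 against 4.86 ± 4.9 TPM (4.61 ± 0.54, adjusted p = 3.3e-07) and Xbp1 rose by 0.63. Plasma cell genes rose in 15 of 23 cases and fell in 1 (17 and 1 adjusted over the list alone, median 1.00, adjusted p = 3.8e-14). Unfolded protein response genes rose in 15 of 26 cases (19 adjusted over the list alone, adjusted p = 9.41e-14) and ER transport genes in 20 of 37 (24 adjusted over the list alone, adjusted p = 3.08e-18). Lysosome genes rose in 14 of 25 with 1 down (15 and 1 adjusted over the list alone, adjusted p = 6.19e-12). Examples from these lists were Edem1 (1.16 ± 0.18), Lman1 (1.14 ± 0.13) and the cathepsin Ctsb (1.13 ± 0.1). Mitosis genes fell in 28 of 33 cases (31 adjusted over the list alone, median -1.68, adjusted p = 3.09e-32) and DNA replication genes in 33 of 35 (34 adjusted over the list alone, median -1.18, adjusted p = 7.26e-32), with Cenpf at -2.84 ± 0.53. The histone gene H2afx, which encodes the variant marked at DNA breaks, was at 108 ± 9.93 against 753 ± 103 TPM (-2.78 ± 0.14). Pax5 (-0.72 ± 0.21), the early B cell factor Ebf1 (-0.67 ± 0.12) and Myc (-1.35 ± 0.17) were lower under PD0332991. In all, 1742 genes passed, 667 up and 1075 down (38.3% up; 51.1% after median-of-ratios scaling), and a fit with replicate number as a block called 2774. With voom weights Pax5 was not called.

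Immunoglobulin genes, which were removed from the tables tested so far, took 5.8% ± 0.511 (SD, n = 5) of TPM in fresh FO cells and 5.38% ± 0.372 in fresh MZ cells. The share was 16.3% ± 1.26 in divided FO cells and 22.6% ± 1.38 in divided MZ cells (n = 4 each). Undivided FO cells had 3.84% ± 0.119 under PD0332991 and 3.81% ± 0.112 under rapamycin, and undivided MZ cells 29.7% ± 2.04 and 17.6% ± 1.93. By two-sided exact permutation tests, adjusted over the 14 comparisons, 12 had adjusted p of 0.0185 or 0.0334, from the smallest p that the group sizes allow (0.00794 and 0.0286). Fresh MZ and fresh FO cells differed by -0.427 points (exact p = 0.167, adjusted p = 0.18), and FO cells under the 2 drugs did not pass either (exact p = 0.714). The share under PD0332991 was above that of divided MZ cells by 7.04 points and above that under rapamycin by 12.1 points. Reads of immunoglobulin segments can be shared between near-identical copies, so single segments are uncertain.

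**Figure D4:**
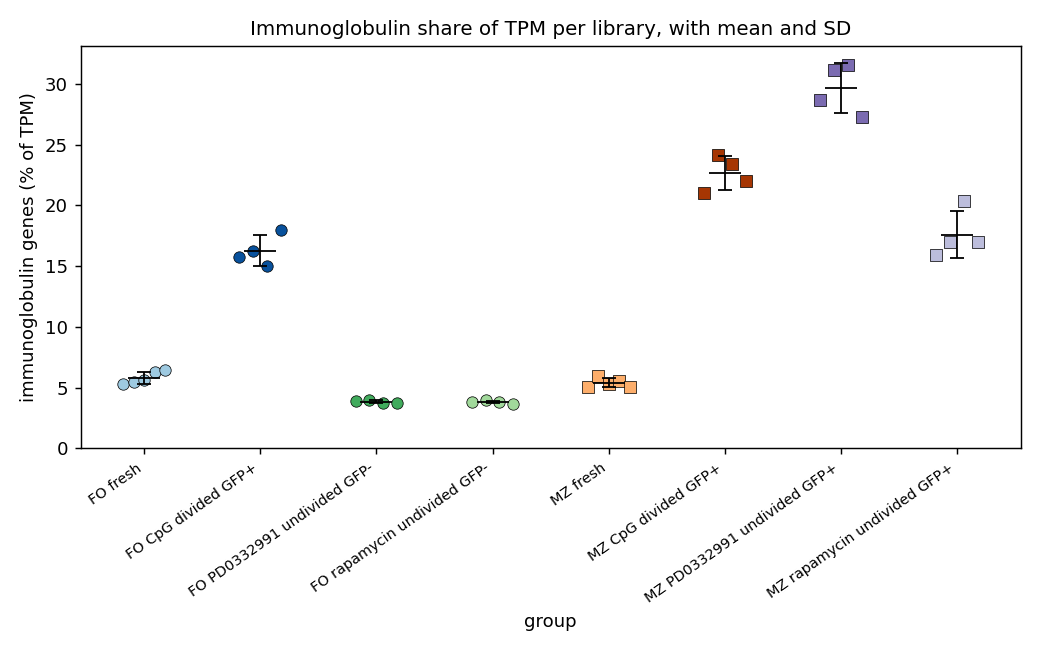
Share of TPM in immunoglobulin genes (percent, from 0), one point per library with mean and SD, in 8 groups. MZ cells under PD0332991 are highest (29.7%) and undivided FO cells lowest (3.84% and 3.81%).

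The heavy chain genes named here were chosen after their values were seen, and isotypes did not all follow the share. Ighm, the IgM constant region, was at 42000 ± 4820 TPM in MZ cells under PD0332991, 31700 ± 1370 TPM in divided MZ cells and 22800 ± 1560 TPM in divided FO cells. Ighd, the IgD constant region, fell from 2600 ± 325 to 5.57 ± 0.179 TPM in divided FO cells (-8.70 ± 0.17) and from 465 ± 79.4 to 3.27 ± 0.436 TPM in divided MZ cells (-6.81 ± 0.17). It was at 2050 ± 304 and 2220 ± 241 TPM in undivided FO cells. Ighg1, the IgG1 constant region, rose to 296 ± 41.4 TPM in divided FO cells (5.70 ± 0.38) and 43.4 ± 7.8 TPM in divided MZ cells (4.48 ± 0.38). It rose in undivided GFP- FO cells as well, to 221 ± 38 TPM under PD0332991 (5.12 ± 0.38) and 178 ± 28.2 TPM under rapamycin (4.76 ± 0.38), and did not pass against divided FO cells (adjusted p = 0.25 and 0.052). In undivided MZ cells it rose to 57 ± 7.23 and 55.5 ± 5.9 TPM. TPM of a constant region does not tell transcripts of switched cells from those of unswitched cells, so switching was not tested. Igj, the joining chain of secreted IgM and a plasma cell gene held only in the tables with immunoglobulin genes, rose by 7.85 ± 0.52 in divided FO cells to 1680 ± 360 TPM (adjusted p = 2.9e-14). It rose by 2.70 ± 0.52 in divided MZ cells from a higher fresh level (99.3 ± 51.5 against 8.72 ± 4.15 TPM).

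The last comparison asked how much of the change from fresh to divided cells was also found in undivided cells under a drug. Of 4988 genes changed at least 1 on the log2 scale in divided MZ cells, 3820 (76.6%, 95% interval 75.4 to 77.8) were also called in the same direction under PD0332991 and 31 in the opposite one. Under rapamycin these were 3580 of 4884 (73.3%, 72 to 74.5) and 36. In FO cells the shares were 3075 of 5473 under PD0332991 (56.2%, 54.9 to 57.5; 104 opposite) and 2925 of 5478 under rapamycin (53.4%, 52.1 to 54.7; 112 opposite). Under PD0332991 the share was 83.3% of genes that rose and 68.9% of genes that fell in MZ cells, and 65% and 42.8% in FO cells. The number of calls also differed by direction: in FO cells 2150 shared rises stood against 870 from independent calls and 925 shared falls against 253, a larger ratio for falls. In MZ cells 2214 rises stood against 686 and 1606 falls against 520, at nearly equal ratios. Xbp1 lay along the line of equal change in MZ cells (4.46 and 4.71) and fell short of it in FO cells (4.18 and 1.89), and Sdc1 did the same in MZ cells (3.43 and 3.79).

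Both changes use the same fresh libraries, which by itself makes them alike. Across genes, which are not independent replicates, the changes correlated at r = 0.848 and 0.83 in MZ cells under PD0332991 and rapamycin and r = 0.711 and 0.704 in FO cells, with covariances of 2.14, 2.1, 1.83 and 1.81. Simulated data with shared fresh libraries and no true change gave r = 0.44, 0.45, 0.44 and 0.44 and covariances of 0.087, 0.095, 0.109 and 0.108, which leaves differences of 2.05, 2, 1.72 and 1.7. With the fresh libraries split so that each change had its own, the shares averaged 66.5%, 63.4%, 44.7% and 43.3% over 20 splits. Each change then rested on fewer fresh libraries, which by itself can lower the share. The part that comes from sharing them was not separated.

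**Figure D5:**
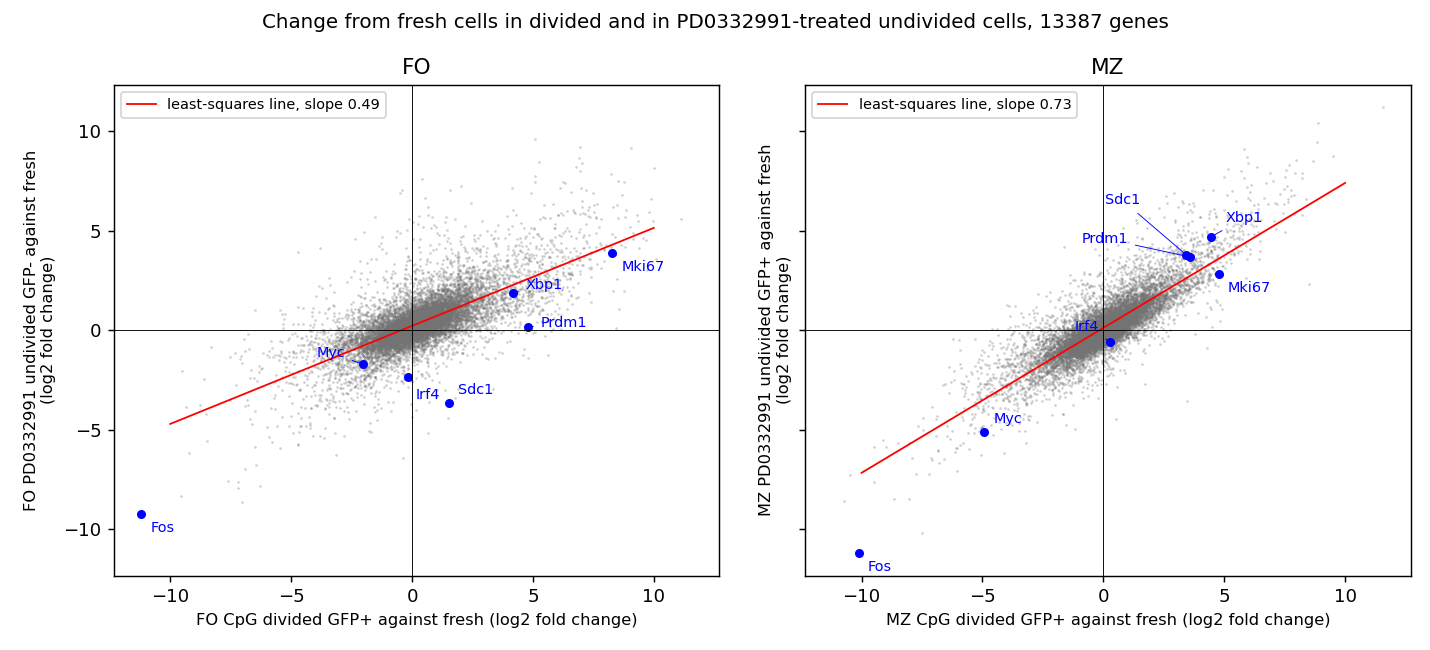
Log2 change under PD0332991 against fresh (y axis) plotted on log2 change of divided cells against fresh (x axis) for 13387 genes, in FO and MZ panels, with the least-squares line in red and key genes in blue. The slope is 0.493 in FO and 0.729 in MZ cells.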

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

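Of the tests below, the T cell counts on log2(TPM + 1), the T cell median in MZ cells and the mitosis count with a scaled offset were chosen after the result was seen; the offset scaled to depth, the lists without sort genes and the fit without 3 fresh libraries are settings chosen after the data were seen, with bounds written before the counts below 1 TPM, and the others were chosen before.

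Among 152 groups of TPM values of key genes and other measures, 11 held a library far from the others of its group; chance alone marks about 1 in 20 groups. Prdm1 was at 44.1 TPM in rapamycin-treated MZ replicate 3 (others 62.9 to 66.1) and Jchain at 26.3 TPM in PD0332991-treated FO replicate 6 (others 9.95 to 11.3). Sdc1 was at 3.3 TPM in rapamycin-treated FO replicate 8 (others 0.386 to 0.805) and at 14.9 TPM in PD0332991-treated MZ replicate 4 (others 16.9 to 17.3). Tnfrsf17 was at 2.09 TPM in fresh FO replicate 2 (others 0 to 0.457) and at 0.375 TPM in PD0332991-treated FO replicate 7 (others 0). Pax5 was at 17.6 TPM in fresh FO replicate 5 (others 34.8 to 40.8) and at 12 TPM in divided FO replicate 5 (others 10.8 to 11). Ciita was at 12.5 TPM in divided MZ replicate 2 (others 14.3 to 14.6), Cr2 at 395 TPM in fresh MZ replicate 4 (others 756 to 861) and Fcer2a at 23.7 TPM in rapamycin-treated MZ replicate 4 (others 7.45 to 8.88).

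The changes against fresh cells differed between MZ and FO cells for 1788 genes in divided cells, 2854 with PD0332991 and 2673 with rapamycin, and for key genes as follows, MZ minus FO on the log2 scale. In divided cells: Prdm1 -1.22, Tnfrsf17 -3.50, Slamf7 -0.69, Bach2 1.45, Cd19 -0.74, Myc -2.91 and Mki67 -3.50. With PD0332991: Prdm1 3.53, Xbp1 2.81, Irf4 1.78, Sdc1 7.45, Pax5 -1.64, Bach2 1.52, Ciita -1.71, Cd19 -1.27, Fcer2a -1.52, Notch2 -2.30, Myc -3.42 and Ccnd2 1.16. With rapamycin: Prdm1 2.32, Xbp1 2.28, Sdc1 4.73, Pax5 -1.44, Bach2 1.63, Ciita -1.60, Cd19 -1.22, Fcer2a -1.20, Notch2 -2.63, Myc -2.34, Mki67 -3.03 and Ccnd2 0.96. Prdm1 was the gate of cultured cells, and culture time and, with drugs, the gate differed between MZ and FO cells.

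T cell transcripts were higher in undivided GFP- FO cells than in fresh FO cells. If T cells were in the gate, which named no CD19 sort, further T cell genes should rise too: in a second list 6 of 10 measured rose under both drugs, such as Trbc2 (7.03 and 6.80), Cd6 and Itk, while Skap1, Txk, Ubash3a and Trac did not pass. Neither bound set beforehand was reached with 6, so T cells may be present and this stays open. On log2(TPM + 1), which the offset does not touch, 10 of 12 T cell markers rose under both drugs, so unequal depth was excluded as the cause. In GFP+ MZ cells under PD0332991 the markers had a median of -0.26 (-0.85 to 0.18 leaving out each library). The rise was thus not shared by these MZ cells. Their gate and culture time differed from those of the FO cells, and no GFP- MZ cells were measured. Induction by the drug in GFP- cells of both subsets therefore cannot be excluded.

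Cell cycle transcripts were higher with rapamycin than with PD0332991 in undivided FO cells. If cells like the divided GFP+ cells without a drug had entered the rapamycin gate, mitosis and plasma cell genes would imply the same share of their RNA. Mitosis genes implied 35.7% (95% bootstrap interval 28.8 to 39.3) and plasma cell genes 1.04% (-0.707 to 1.52). These values argue against mixing with cells like those without a drug. The gate itself left out GFP+ cells, which made a low plasma cell share likely in advance. Divided cells from rapamycin cultures were not measured, so mixing with them was not tested. With an offset scaled to depth 30 mitosis genes were still higher with rapamycin, so the offset was excluded. A difference between the drugs stays possible at that count of 30, as do divided GFP- cells, which were not tested.

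In MZ cells under PD0332991 against fresh, genes below 1 TPM on average were called 244 times, 195 of them up. With an offset scaled to depth 129 of them (52.9%) stayed called, and of the 206 genes then called only 81 were up, with the median change of the 244 going from 1.88 to 1.08. The excess of increases was therefore lost with that offset, while the share kept fell between the bounds set beforehand, so whether the offset makes up the calls stays open. Without the 3 fresh libraries that stand apart 195 (79.9%) stayed called, which excludes those libraries as the main cause.

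Other splits of the samples into mixed groups asked how often as many genes are called. The real split is counted among them, and shares were not adjusted over the comparisons. Mixed groups hold unlike cell states, which can widen their spread, so a low share does not by itself exclude chance. The real count was reached by 1 of 100 splits for FO CpG (highest other 6921), MZ CpG (6383) and FO PD0332991 (5416) against fresh. The same held for MZ PD0332991 (5277), FO rapamycin (5378) and MZ rapamycin (4984) against fresh and for the CpG interaction (969). For the PD0332991 interaction it was reached by 2 of 100, and another split called more genes (3668) than the real one (2854). Only 1 of 35 splits, the lowest share possible, reached it for MZ against FO CpG (5), FO PD0332991 against CpG (5) and MZ PD0332991 against CpG (10). That share also held for FO rapamycin against CpG (5), MZ rapamycin against CpG (55) and PD0332991 against rapamycin in FO (1) and MZ cells (6). Larger shares were found for fresh MZ against fresh FO (9 of 100, highest other 3760) and the rapamycin interaction (5 of 100, highest other 4905). For the number of called genes chance cannot be excluded there, and splits with that many called genes point to structure of the samples. Which libraries carry it was not tested. This bears on the count and not on single markers of the fresh subsets, such as S1pr3 (5.05 ± 0.21) and Cd9 (4.71 ± 0.15), or on the marginal zone list without the genes of the sort gates (adjusted p = 8.48e-24).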

How the results depend on the processing

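Of the tests of the processing, the offset scaled to depth, voom weights, the lists without sort genes and the fits without 3 fresh libraries were chosen after the result was seen. Of 173 alternatives to the counts, apart from leaving out single libraries, 161 stayed within 1.5 times the main count, and so did 173 of 174 fits that left out 1 library. With only the compared samples, where fewer samples estimate the error, counts were 1265 for MZ against FO fresh, 1891 for MZ against FO CpG, 940 for FO PD0332991 against rapamycin, 1161 for the CpG interaction and 1603 for the rapamycin interaction. With no filter more genes are tested, and counts against fresh were 14587 (FO CpG), 13102 (MZ CpG), 9736 (FO PD0332991), 12725 (MZ PD0332991) and 10717 (MZ rapamycin). With replicate number as a block, PD0332991 against rapamycin gave 760 in FO and 2774 in MZ cells, and MZ against FO fresh gave 3532; the cause was not tested. A possible link by replicate number was checked on deviations of each gene from its group mean, not on the log2 values themselves. These deviations correlated at 0.05 to 0.43 (median 0.2) between fresh FO and MZ libraries of the same number, so a link is not excluded. Between same-numbered libraries of the other pairs of groups they correlated at -0.17 to 0.16. Estimated correlations called 176 of the lists against 281 of 544 in the main test, and lists without sort genes 279, with 4 calls lost and 2 gained. The shared change for FO PD0332991, FO rapamycin, MZ PD0332991 and MZ rapamycin was 58.7%, 58%, 82.3% and 78.2% on log2(TPM + 1), 49.8%, 47.2%, 66.6% and 64.3% with no size threshold, and 44.7%, 43.3%, 66.5% and 63.4% with fresh libraries split. With the offset scaled to depth it was 54% and 51.4% in FO cells; the cause was not tested.

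Leaving out each library gave 2160 to 2911 genes for MZ against FO fresh, 7726 to 8175 for FO CpG and 6966 to 7376 for MZ CpG against fresh. It gave 673 to 821 for MZ against FO CpG, and 257 to 331 for FO PD0332991 against rapamycin, the lowest without PD0332991 replicate 6. The shared change was 48.9 to 58.1%, 47 to 55.9%, 71.1 to 77.8% and 69.1 to 75.6% in the order above, and fewer samples are in each fit. The immunoglobulin share passed in 11 to 12 comparisons. Without the 3 fresh libraries counts against fresh were 8330 (FO CpG), 8089 (MZ CpG), 5642 (FO PD0332991), 7149 (MZ PD0332991), 5377 (FO rapamycin) and 7077 (MZ rapamycin), 2705 between fresh subsets, and 2320, 3313 and 2893 for the interactions. Of 17512 alternative values of named genes 16843 kept their direction and side of the threshold, 552 lost and 114 gained a call, and 3 reversed. Those were Oas2 in the CpG interaction, 2.19 in the main test and -0.36 on log2(TPM + 1) or -0.28 with scaling as well, and Mki67 in the PD0332991 interaction, -1.04 (not called) and 1.01 on log2(TPM + 1) with scaling; the cause was not tested. Depth was not varied on its own in the simulated data, so its part in missed changes is not known. Far fewer genes were changed there than were called in the real data. Of planted log2 changes, 19.7% of those of 0.5 and 91% of those of 2 were recovered for MZ PD0332991 against fresh.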

Other observations

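Of the tests below, those without the 3 fresh libraries that stand apart were chosen after the result was seen, as were the genes named for their TPM. Survival genes of the BCL2 family moved both ways. Bcl2l1, which blocks cell death, rose in divided FO cells (4.1 to 74.1 TPM) while Bcl2, which does the same, was at 11.8 against 30.7 TPM, and the list had 9 of 16 up and 3 down (adjusted p = 0.556). Divided MZ cells had 5 up and 5 down (adjusted p = 0.242), and against divided FO cells 3 of 16 were lower (5 adjusted over the list alone, adjusted p = 0.00317), with Bcl2 at -1.09 ± 0.17. Fresh MZ cells had 8 up and 0 down against fresh FO cells, also adjusted over the list alone, with Bid, which promotes death, up 1.72 ± 0.13 (adjusted p = 0.0129; adjusted p = 0.09 with an estimated correlation). Without the 3 fresh libraries that stand apart 7 were up and 3 down, and the list was not called (adjusted p = 0.146). Of 15 p53 targets 8 rose and 4 fell in divided FO cells (adjusted p = 0.753), with the growth arrest gene Phlda3 up 6.11 ± 0.64 and the kinase Plk2 at -6.27 ± 0.32. Against divided FO cells, 2 fell in divided MZ cells, Plk2 and Cdkn1a (-2.52 ± 0.34 and -1.19 ± 0.31), also adjusted over the list alone (adjusted p = 0.000714).

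Germinal centre markers were not called in any comparison; in divided FO cells 3 of 8 rose and 3 fell (adjusted p = 0.666), with Aicda up 4.71 ± 0.57 and Bcl6, the germinal centre repressor, at -4.49 ± 0.42. Immature and transitional markers were lower in fresh MZ than fresh FO cells, with 2 of 4 down, or 1 up and 2 down adjusted over the list alone (adjusted p = 0.0141; adjusted p = 0.09 with an estimated correlation). They were Cd93 (-2.41 ± 0.32), a gene used in the sort, and Vpreb3, a surrogate light chain partner (-2.26 ± 0.19); without Cd93 the list was not called (adjusted p = 0.175). Cd24a fell in undivided FO cells from 289 to 24.7 and 25.5 TPM. B-1 markers were not called in any comparison; in fresh MZ cells 3 of 6 rose, such as Cd5 (2.43 ± 0.62), and the list had adjusted p = 0.426. Mitochondrially encoded genes had 4 of 13 up in MZ cells under PD0332991 against rapamycin (6 adjusted over the list alone), such as mt-Nd2 (0.70 ± 0.23; adjusted p = 6.8e-05; adjusted p = 0.431 with an estimated correlation).

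Of 7 macrophage, monocyte and dendritic cell markers 2 rose in FO cells under PD0332991 against fresh (adjusted p = 0.812), such as the integrin Itgam (2.57 ± 0.38). Against rapamycin in FO cells this list was called up (median 0.75, adjusted p = 0.0245; adjusted p = 0.191 with an estimated correlation). There 1 of 7 rose (2 adjusted over the list alone), Itgax, at 0.336 TPM against 0 TPM, and on log2(TPM + 1) the list was not called (adjusted p = 0.108). Erythroid and platelet markers were not called in any comparison; in divided FO cells 3 of 6 fell, such as the globin gene Hbb-bs (-3.76 ± 1.4), whose reads can be shared with near-identical copies (adjusted p = 0.48). The sum of erythroid markers ran from 7.52 to 1530 TPM among fresh FO libraries and from 8.34 to 388 TPM among FO libraries under PD0332991.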
